A study of Homo sapiens with 7 samples.

How the data were processed

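Polyadenylated RNA from HEK293T cells was measured in 7 libraries: 2 controls with 4 µg of empty vector, 2 with IL1RN guides and 3 with HBG guides, the guide groups with 3 µg of Cas9-VP64 plasmid and 4 guide plasmids at 250 ng each, all harvested on day 3. The deposited table holds raw whole-number read counts per RefSeq transcript, 1 column per library, with no normalization. The submitters' processing notes name CASAVA, Bowtie 0.12.9, DESeq 1.10.1 and the builds hg19 and GRCh37. Strand, read length and the treatment of reads that match several transcripts are not given in the sources used here. The 3 pairs of transcripts with identical sequence had 18 values with enough reads, of which 1 pair had equal counts in a library, with a mean squared standardized difference of 1.3. Positions are GRCh38, from the GENCODE annotation, and served for location alone. Total counts per library were 22271134 to 61513902, and the 5 most abundant transcripts held 2.29 to 2.83% of them. Of 40709 transcripts, 39324 were matched to a symbol through the RefSeq gene table and 516 through GENCODE, and 869 had none. The symbols numbered 23526, of which 7723 had several transcripts.

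Before the data were examined, the comparisons, the tests, the alternatives, the rule for named genes and the gene lists were fixed. The planned model was the edgeR 4.0.16 quasi-likelihood test on transcripts as deposited, in R 4.3.3, with TMM normalization, filterByExpr by group (minimum count of 10), group as the only term, all 7 libraries in 1 fit and Benjamini-Hochberg adjusted p under 0.05. It tested 29986 transcripts with 4 residual degrees of freedom and a biological coefficient of variation of 34.3%. The 4 contrasts were IL1RN guides against control, HBG guides against control, IL1RN guides against HBG guides, and the mean of both guide groups against control. CPM values use TMM-scaled library sizes, with a prior count of 2 where logged. The targeted genes were given in every library with 95% Poisson counting intervals. Ratios to a group with 0 reads were set against 3 counts over the group, and exact permutation tests over all splits of the libraries were one-sided.

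A model with the library factor was added after the data were seen. The factor is the score of each library on the first axis of the deviations from the group means, used as a covariate on counts summed per gene symbol. It tested 17061 genes with 3 residual degrees of freedom and a biological coefficient of variation of 12.2%, against 34.8% without the factor. A trend on GC content and length, a natural spline with 5 degrees of freedom, removed 50.5% of the variance in the alternatives that use it, also added after the data were seen.

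Named genes were the targeted genes; up to 10 genes per direction with the largest log2 fold change among those past the threshold, with mean log2 CPM of at least 1 and groups that do not overlap (for the mean contrast, all 5 guide libraries on 1 side of both controls); where fewer than 5 passed, the 5 with the smallest unadjusted p in each direction, as values only; and up to 4 members of each list with the smallest adjusted p. Other names are marked as chosen after their values were seen.

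Gene lists were tested per gene symbol with limma 3.58.1 camera on voom values, with a preset inter-gene correlation of 0.01, and also with camera with an estimated correlation and with fry, adjusted over the lists of each comparison. Lists with under 5 tested members were given as values. The 28 lists were the targeted genes, globin genes not targeted, neighbours in the IL1 cluster, neighbours of the beta-globin cluster, fetal globin regulators, erythroid markers, monocyte and neutrophil markers, fibroblast markers, lymphocyte markers, interleukin 1 receptor signalling components, NF-kB response genes, interferon-stimulated genes, p53 target genes, unfolded protein and integrated stress response, heat shock proteins, immediate early genes, cholesterol synthesis and uptake, fatty acid synthesis, glycolysis and hypoxia response, mitotic genes, DNA replication genes, replication-dependent histone genes, ribosomal protein genes, nuclear-encoded respiratory chain genes, mitochondrially encoded genes, spliceosome components, transcriptional coactivators recruited by VP16-type domains, and lineage regulators low in kidney lines.

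The alternatives fixed in advance were DESeq2 size factors, library size only, a filter of at least 1 count in any library, a filter of at least 10 counts in every library of a group, DESeq2 1.42.0, the edgeR likelihood ratio test, robust quasi-likelihood, only the groups compared, the replicate number as a block, gene-symbol sums, stricter thresholds and leaving out each library in turn. Where this leaves a group with 1 library, that library is assumed to vary like the other groups. The overlap of calls was set beside 100 simulated draws of unchanged guide groups.

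The models were tested on simulated data with known changes. Counts were drawn independently for each gene, around a common mean for the planned model and around the library factor for the other. The planned draws thus lacked the axis shared by the real libraries, and the others were built on the factor that is then fitted. The shares recovered therefore do not give the power in these data. For the mean of both guide groups, the planned model recovered 1.49% of transcripts changed 2-fold, 47.8% changed 4-fold and 97% changed 8-fold; with the library factor and gene sums, 100% were recovered at each size, with 13 unchanged genes called among 213. For IL1RN guides against HBG guides these were 0, 32.8 and 83.3%, and 61.2, 98.5 and 100% with the factor, with 25 unchanged genes called among 198. A list of 30 genes raised 2-fold was found by camera (adjusted p = 1.8e-105), and 0 of 24 other lists passed. All these lists were random and their genes were drawn independently around the library factor. False calls from correlation between the genes of a list were therefore not tested. Figures were drawn with matplotlib 3.10.9. All 7 columns of the table were used.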

Results

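Messenger RNA was sequenced from 7 libraries of HEK293T cells, a human embryonic kidney line that carries a viral large T antigen. The cells were transfected with plasmids for Cas9-VP64, a Cas9 fused to a transcriptional activation domain, and for guide RNAs that direct it to a promoter. IL1RN guides were used in 2 libraries and HBG guides, aimed at HBG1 and HBG2, in 3, and 2 control libraries received an empty vector. The labels leave open whether the control cells also received Cas9-VP64. All cells were harvested on day 3. The libraries held 41538115 and 44136382 counts in the controls, 22271134 and 39118210 with IL1RN guides, and 24624546, 61513902 and 44377291 with HBG guides, over 40709 RefSeq transcripts. Below, edgeR and DESeq2 p-values of single genes measure the spread between the biological duplicates or triplicates that the series text describes. Camera p-values with the preset correlation compare the genes of a list with the other genes and do not measure the spread of the list between libraries. Exact permutation p-values are limited by the number of splits. Intervals and limits of a count of 0 cover counting error only. Values with ± are SD for levels and standard errors for log2 fold changes.

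The comparison of IL1RN guides with control asked whether the targeted gene was switched on and what else changed with it. IL1RN, the gene of the interleukin 1 receptor antagonist, a secreted inhibitor of interleukin 1 signalling, was nearly silent in control cells and clearly expressed with its guides. The gene spans 113107214 to 113134016 of chromosome 2 (GRCh38, plus strand). Its 4 transcripts (NM_000577, NM_173841, NM_173842 and NM_173843, with 4 to 6 exons) start at 113117897, 113117897, 113127561 and 113117893. Together the transcripts held 217 and 404 reads with IL1RN guides, 6 and 0 reads in the controls, and 0, 2 and 0 reads with HBG guides. The mean level was 11.7 ± 1.27 CPM (reads scaled to library size; n = 2) with IL1RN guides and 0.0786 ± 0.111 CPM (n = 2) in control. From pooled reads the ratio was 164, with a 95% counting interval of 75 to 449. All 6 control reads came from control replicate 1. Without this library the control had 0 reads, and IL1RN was at least 184-fold higher, set against 3 counts over the group. The exact one-sided permutation p against control was 0.167, the smallest that 6 splits allow, and 0.0476 against all other 5 libraries, the smallest that 21 splits allow. In the edgeR quasi-likelihood test the log2 fold change of NM_000577 was 6.29 ± 0.86, with an adjusted p of 0.51. It was 10.04 ± 0.74 for NM_173841, 7.61 ± 0.74 for NM_173842 and 6.59 ± 0.8 for NM_173843. Summed per gene symbol it was 7.29 ± 0.98. Each of these also had an adjusted p of 0.51. NM_173841 had 0 reads in both controls, so its value depends on the prior count.

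HBG1 and HBG2, the fetal gamma-globin genes, which red cell precursors express and kidney cells keep silent, had reads in all 3 libraries with HBG guides and in no other library. HBG1 (NM_000559; chromosome 11, 5248079 to 5249859, minus strand, 3 exons) had 4, 3 and 6 reads with its guides. HBG2 (NM_000184; chromosome 11, 5253190 to 5254811, minus strand, 3 exons) had 6, 5 and 6 reads. The 2 genes are nearly identical in sequence, so reads may be split between them by the counting. Together they held 10, 8 and 12 reads, or 0.243 ± 0.124 CPM (n = 3), and 0 reads in each of the other 4 libraries. Their sum was at least 6.03-fold higher than in control, set against 3 counts over the group (HBG1 at least 2.61-fold and HBG2 at least 3.42-fold). The exact one-sided permutation p was 0.1 against control, the smallest that 10 splits allow, and 0.0286 against the other 4 libraries, the smallest that 35 splits allow. Both transcripts lie below the count filter of the edgeR test. Leaving out control replicate 2 lowered the bounds from 1.39 to 0.21 (HBG1) and from 1.77 to 0.6 (HBG2) on the log2 scale, and leaving out control replicate 1 lowered them to 0.55 and 0.94, since the floor then rests on fewer reads.

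**Figure D1:**
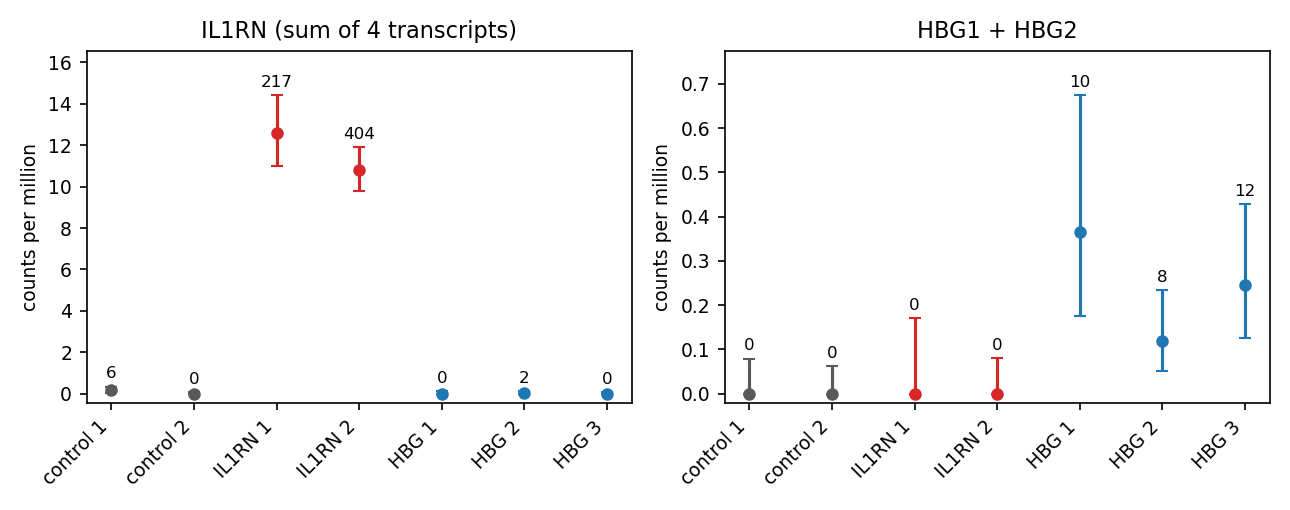
Levels of the targeted genes in each library, as CPM on linear axes, with the read numbers above the points. Bars are 95% Poisson counting intervals, and for libraries with 0 reads they end at the limit of 3 counts. IL1RN stood at 12.6 and 10.8 CPM with its guides, and HBG1 with HBG2 at 0.366, 0.119 and 0.245 CPM with theirs.

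The libraries differed along 1 dominant axis that parted the 2 controls. It held 86.4% of the variance between libraries, differences between groups included, and its weights rose with GC content (Spearman 0.64 across transcripts, which are not independent replicates). The first axis of the deviations from the group means held 82.6% of the variance within groups, and on its standardized score, given for every library, the 2 controls lay on opposite sides, 2.09 apart, while the mean of the guide groups lay 0.23 from the control mean. Both IL1RN libraries (scores of -1.43 and -0.59) lay on the side of control replicate 1 (-1), and all 3 HBG libraries (0.73, 0.89 and 0.3) on the side of control replicate 2 (1.09). In the lowest GC decile, with a median of 37.7% GC, control replicate 1 stood 0.472 above and control replicate 2 stood at -0.618 relative to the mean of all libraries on the log2 scale. Each comparison is therefore given as planned, with group alone, and also per gene symbol with the score as a covariate, called the library factor. The library factor was added after the data were seen. It is estimated from the same libraries, so its p-values may be too small.

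**Figure D2:**
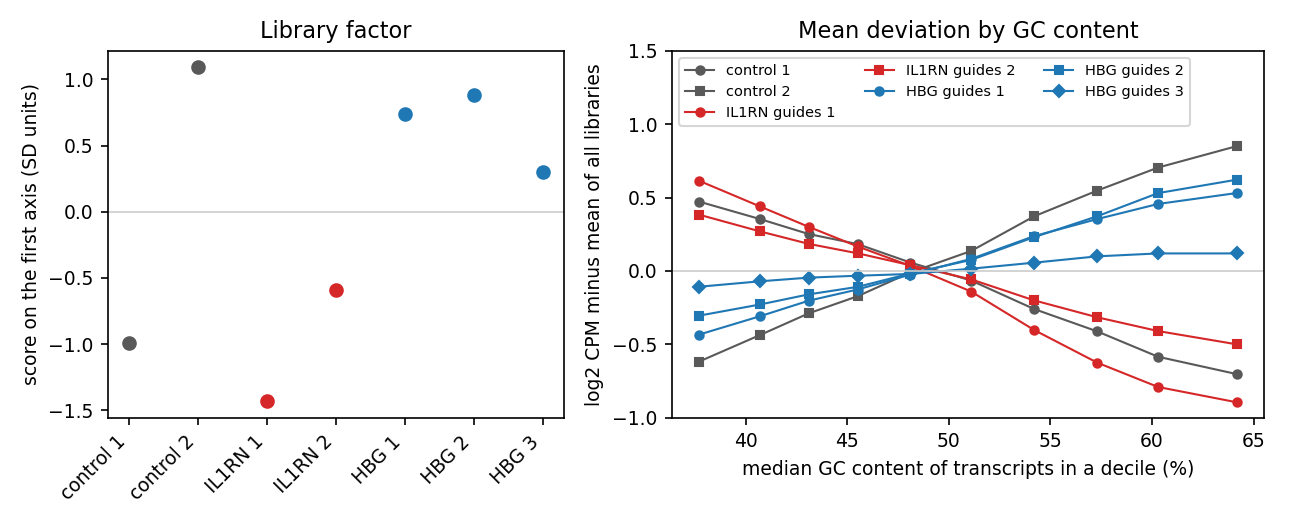
Left, the score of each library on the first axis of the deviations from the group means, in SD units; right, the mean deviation of log2 CPM from the mean of all libraries by decile of transcript GC content, with 1 line per library. Control replicates 1 and 2 lie at -1 and 1.09 on the score and run in opposite directions with GC content, the former together with both IL1RN libraries and the latter with all 3 HBG libraries.

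Besides IL1RN, cells with IL1RN guides differed from control in lower levels of IL32, IFI44L, IFI6, OAS3 and TNFRSF9 once the library factor was in the model. IL32, an inflammatory cytokine, fell from 18.3 ± 2.99 CPM (n = 2) to 2.13 ± 0.167 CPM (n = 2), a log2 fold change of -3.24 ± 0.22 (edgeR, adjusted p = 0.00018). IFI44L, an interferon-induced gene, fell from 7.32 ± 3.95 to 0.515 ± 0.00634 CPM (-4.28 ± 0.44, adjusted p = 0.0044). IFI6, an interferon-induced mitochondrial protein (-2.33 ± 0.27, adjusted p = 0.0099), OAS3, an enzyme that responds to double-stranded RNA (-2.08 ± 0.24, adjusted p = 0.011), and TNFRSF9, a costimulatory receptor (-1.89 ± 0.25, adjusted p = 0.027), were also lower, each in 2 of 2 libraries below both controls. IL1RN rose by 6.8 ± 0.53 (adjusted p = 0.00044), a call that DESeq2 did not make (6.91, adjusted p = 1). These 6 genes, 1 higher and 5 lower, were all that passed among 17061, with 765 at an unadjusted p under 0.05 where chance gives 853.

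In the planned edgeR model 0 of 29986 transcripts passed between IL1RN guides and control, with 1250 at an unadjusted p under 0.05 where chance gives 1499. DESeq2 called 15 transcripts (2609 unadjusted) and the edgeR likelihood ratio test 15 (2752 unadjusted), in both cases 4 higher and 11 lower. The planned count rose from 0 to 15221 without control replicate 1. Among transcripts with the smallest unadjusted p, values were 1.06 for RORB, a nuclear receptor, and 1.09 for KITLG, a stem cell growth factor, on the higher side. On the lower side they were -2.11 ± 0.35 for TNFRSF9, -3.82 for IFI44L, -1.63 for IRF9 and -3.25 for OAS3. With the library factor, the count of 6 became 258 without control replicate 1, 13 without control replicate 2, 13 without IL1RN replicate 1, 160 without IL1RN replicate 2 and 4 without HBG replicate 2. IFI6 no longer passed without control replicate 1 (-0.91, adjusted p = 0.3) or HBG replicate 2 (-2.32, adjusted p = 0.085), nor TNFRSF9 without control replicate 1 (-1.17, adjusted p = 0.15), nor OAS3 without HBG replicate 2 (-2.08, adjusted p = 0.085), while IL32, IFI44L and IL1RN passed in all 7 such fits, IL1RN with values of 5.73 to 11.65, the highest without control replicate 1.

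As a group, interferon-stimulated genes, which cells switch on in antiviral defence, were lower with IL1RN guides. Of 39 tested genes, 33 had negative log2 fold changes in the planned model, with a median of -0.61 (camera, adjusted p = 2.4e-05; adjusted p = 0.77 with an estimated correlation). None passed over all genes and 6 were lower when adjusted over the list alone. With the library factor, 37 were negative with a median of -0.56 (camera, adjusted p = 1.3e-29; adjusted p = 0.045 with an estimated correlation), 3 were lower over all genes and 18 when adjusted over the list alone. Genes that respond to NF-kB, a transcription factor of inflammation, had a median of -0.5 over 23 tested (camera, adjusted p = 0.047; adjusted p = 0.77 with an estimated correlation), with 2 lower adjusted over the list alone and 0 over all genes. With the factor the median was -0.33 (camera, adjusted p = 3.9e-06; adjusted p = 0.56 with an estimated correlation), with 4 lower adjusted over the list alone, among them IL32 and BIRC3, and 1 over all genes. In the planned model neither list passed without control replicate 1 (adjusted p = 0.47 for each), and the NF-kB list also missed without IL1RN replicate 2 (adjusted p = 0.16); with the factor the NF-kB list missed without control replicate 1 (adjusted p = 0.2).

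Ribosomal protein genes and nuclear-encoded respiratory chain genes moved with the library axis. In the planned model their medians were 1.12 (74 of 74 positive; camera, adjusted p = 2e-16) and 0.81 (34 of 41 positive; camera, adjusted p = 2.8e-05) with IL1RN guides against control, each with an adjusted p of 0.77 with an estimated correlation. With the library factor the medians were 0.19 (camera, adjusted p = 1e-04; adjusted p = 0.82 with an estimated correlation) and 0.02 (camera, adjusted p = 0.81). Mitotic genes had a median of 0.34 over 33 genes (camera, adjusted p = 0.0078; adjusted p = 0.77 with an estimated correlation), and -0.04 with the factor, which did not pass. Cholesterol synthesis genes, at -0.01 in the planned model, had a median of -0.16 over 25 genes with the factor (camera, adjusted p = 0.0029; adjusted p = 0.56 with an estimated correlation).

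HBG guides against control asked the same of the gamma-globin guides. IL32, TNFRSF9 and OAS3 had the smallest adjusted p. With the library factor, IL32 fell to 1.52 ± 0.191 CPM (n = 3) from 18.3 ± 2.99 CPM (n = 2), a log2 fold change of -3.47 ± 0.18 (edgeR, adjusted p = 7.9e-06). TNFRSF9 fell to 5.47 ± 1.51 from 33.3 ± 3.26 CPM (-2.71 ± 0.21, adjusted p = 0.00025) and OAS3 to 3.09 ± 0.625 from 11.7 ± 9.21 CPM (-2.2 ± 0.17, adjusted p = 0.00025). IFI44L (-2.71 ± 0.32, adjusted p = 0.015) and IFI6 (-1.83 ± 0.23, adjusted p = 0.016) also fell. NFKBIA, the inhibitor of NF-kB that is itself a target of it, fell by 1.05 ± 0.13 on the log2 scale (adjusted p = 0.018).

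TAPBP, ERAP2, VCAM1 and RELB were among the other genes lower with HBG guides. TAPBP, which loads peptides onto MHC class I, fell by 0.97 ± 0.13 (adjusted p = 0.019), and ERAP2, which trims these peptides, by 1.04 ± 0.16 (adjusted p = 0.042). VCAM1, an adhesion molecule, fell by 3.68 ± 0.45 at a low level, from 1.14 to 0.0774 CPM (adjusted p = 0.016; not called by DESeq2, which gave it no adjusted p), and RELB, an NF-kB subunit, fell by 1.58 ± 0.21 (adjusted p = 0.019). PLA2G4C, a phospholipase, and TMSB4X, an actin-binding peptide, fell by 1.42 ± 0.2 and 1.03 ± 0.15. COL14A1, a collagen, rose by 1.1 ± 0.15 (adjusted p = 0.021). B2M, the light chain of MHC class I (-0.94 ± 0.13), and the matrix protein TNC (-2.01 ± 0.26), both chosen after their values were seen, complete the 15 genes, 1 higher and 14 lower of 17061, with 1455 at an unadjusted p under 0.05. For 10 of these 15 genes all 5 guide libraries lay below both controls. Of the 5, 3 did so for RELB, B2M and TMSB4X and 4 for TNC, and COL14A1 lay above both in 4. With HBG guides RELB (3.99, 5.41 and 2.71 CPM) overlapped the controls (3.5 and 16.7 CPM). TNC (8.23, 17.7 and 6.5 CPM) overlapped them as well (14.5 and 52.4 CPM). For B2M and TMSB4X all HBG libraries lay below both controls.

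The planned edgeR model called 0 of 29986 transcripts between HBG guides and control, with 700 at an unadjusted p under 0.05. DESeq2 called 13, all lower (1138 unadjusted), and the edgeR likelihood ratio test 18, all lower (1357 unadjusted). Summed per gene symbol, 1 gene passed, IL32 (lower, adjusted p = 0.038). Among the smallest unadjusted p, values were -2.61 ± 0.31 for TNFRSF9 (adjusted p = 0.24), -2.41 for IFI6, -3.08 for IFI44L and -2.03 for PTX3, and 0.95 for RORB and 1.18 for HAS2, which makes hyaluronan. The planned count rose to 11123 without control replicate 2 and to 1 without control replicate 1, and the count of 15 with the factor became 186 without control replicate 2, 113 and 121 without IL1RN replicates 1 and 2, and 7, 5 and 4 without HBG replicates 1, 2 and 3, with IL32, OAS3 and TNFRSF9 called in all 7 fits. Each of the other 12 missed at least once: NFKBIA, RELB, TAPBP, COL14A1, B2M, PLA2G4C, TMSB4X and ERAP2 without any 1 of the HBG libraries (adjusted p of 0.06 to 0.35), IFI6 and VCAM1 without HBG replicate 2 (0.18 and 0.097) or 3 (0.053 each), TNC without HBG replicate 3 (0.053), IFI44L (-2.51), VCAM1 (-2.47), RELB (-0.54), TAPBP (-0.45), COL14A1 (1.18) and ERAP2 (-1.27) without control replicate 2, which moved IFI6 to -2.96 and TMSB4X to -1.77, and B2M (-0.8), TMSB4X (-0.74) and ERAP2 (-0.93) without control replicate 1; B2M and TMSB4X also missed once the GC content and length trend was removed.

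Of the 39 interferon-stimulated genes, 38 had negative log2 fold changes with HBG guides in the planned model, with a median of -0.86 (camera, adjusted p = 2.8e-19; adjusted p = 0.24 with an estimated correlation), 0 lower over all genes and 10 when adjusted over the list alone. With the factor 36 were negative, with a median of -0.61 (camera, adjusted p = 6e-20; adjusted p = 0.091 with an estimated correlation), 3 lower over all genes and 19 when adjusted over the list alone. NF-kB response genes had a median of -0.34 (camera, adjusted p = 2.1e-05; adjusted p = 0.24 with an estimated correlation), 1 lower over all genes and 3 adjusted over the list alone, and the list missed without control replicate 2 (adjusted p = 0.17). With the factor the median was -0.43 (camera, adjusted p = 4.8e-09; adjusted p = 0.59 with an estimated correlation), with 4 lower over all genes and 7 adjusted over the list alone. Ribosomal protein genes (median of -1.37, 74 of 74 negative; camera, adjusted p = 2.8e-19) and respiratory chain genes (median of -1.13, 37 of 41 negative; camera, adjusted p = 4.8e-09) each had an adjusted p of 0.53 with an estimated correlation in the planned model, on the side of the library axis on which control replicate 2 lay. With the factor the medians were -0.33 (camera, adjusted p = 2.1e-17; adjusted p = 0.81 with an estimated correlation) and -0.34 (camera, adjusted p = 7.9e-12; adjusted p = 0.59 with an estimated correlation). Of the respiratory chain genes 13 were lower adjusted over the list alone with the factor and 0 over all genes, with -0.56 for NDUFB9 and -0.57 for NDUFA6, subunits of complex I. Glycolysis and hypoxia genes had a median of 0.22 over 30 genes (camera, adjusted p = 0.02; adjusted p = 0.53 with an estimated correlation) and 0.13 with the factor (camera, adjusted p = 0.0033; adjusted p = 0.81 with an estimated correlation).

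**Figure D3:**
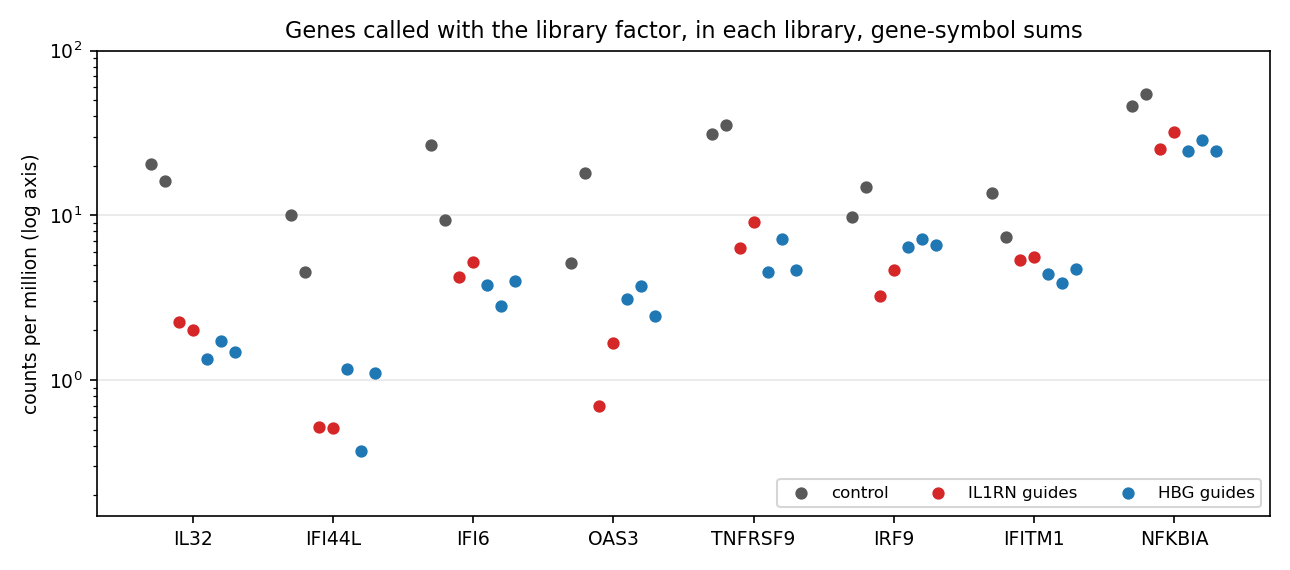
CPM of 8 genes called with the library factor, on a log axis, with 1 point per library, coloured by group. The 8 genes were chosen after their values were seen; for each, all 5 guide libraries lay below both controls, with group means for IL32 of 18.3 CPM in control, 2.13 with IL1RN guides and 1.52 with HBG guides.

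IL1RN guides against HBG guides holds Cas9-VP64 and the number of guide plasmids constant, and it tests whether the 2 sets of guides had different effects. IL1RN itself differed: 621 pooled reads with its guides stood against 2 with HBG guides, a ratio of 817 (95% counting interval 225 to 6760). With the library factor its log2 fold change was 8.47 ± 0.91 (edgeR, adjusted p = 0.022), the 1 gene past the threshold of 17061, with 606 at an unadjusted p under 0.05. The call was lost without IL1RN replicate 1 (7.05, adjusted p = 0.74) or 2 (5.85, adjusted p = 0.48), or HBG replicate 2 (10.79, adjusted p = 0.63) or 3 (7.73, adjusted p = 0.07), and with DESeq2, and the count of 1 became 260 without control replicate 1, 223 without control replicate 2, 324 without IL1RN replicate 2 and 0 without IL1RN replicate 1, HBG replicate 2 or HBG replicate 3. HBG1 and HBG2, with 0 reads in both IL1RN libraries, stood below the count filter.

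Ribosomal protein genes and respiratory chain genes had large positive values here, along the same axis that parted the controls. Their medians were 2.49 (74 of 74 positive; camera, adjusted p = 2.9e-21) and 2.05 (35 of 41 positive; camera, adjusted p = 8.9e-08), each with an adjusted p of 0.93 with an estimated correlation; 0 passed over all genes, and 70 and 30 were higher adjusted over the list alone. With the factor the medians were 0.52 (camera, adjusted p = 3.3e-31) and 0.36 (camera, adjusted p = 3e-12), each with an adjusted p of 0.74 with an estimated correlation. Adjusted over the list alone, 0 and 2 genes passed, and 0 over all genes. Across transcripts, which are not independent replicates, the difference between the controls and that between IL1RN and HBG guides had a Pearson r of 0.94. Mitotic genes had a median of 0.66 (camera, adjusted p = 0.016; adjusted p = 0.93 with an estimated correlation) and -0.13 with the factor. Spliceosome genes had a median of 0.17 without and 0.17 with the factor, which passed in the latter (camera, adjusted p = 0.0013; adjusted p = 0.74 with an estimated correlation), and 12 of 33 were higher adjusted over the list alone in the planned model, 0 over all genes. Glycolysis genes (-0.2; camera, adjusted p = 0.0021), cholesterol genes (-0.08; camera, adjusted p = 0.036) and interferon-stimulated genes (-0.09; camera, adjusted p = 0.012) were lower with the factor, each with an adjusted p of 0.74 with an estimated correlation, the last not without control replicate 1 (adjusted p = 0.77), control replicate 2 (adjusted p = 0.91) or IL1RN replicate 2 (adjusted p = 0.1).

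In the planned edgeR model 0 of 29986 transcripts passed between IL1RN and HBG guides, with 9742 at an unadjusted p under 0.05 and a smallest adjusted p of 0.15. DESeq2 called 3607 (2709 higher and 898 lower; 12232 unadjusted) and the edgeR likelihood ratio test 2623 (2345 higher and 278 lower; 11664 unadjusted). With the factor 0 transcripts passed and 1021 had an unadjusted p under 0.05. Values among the smallest p were 3.25 ± 0.71 for RPS27L, a ribosomal protein paralog, 1.9 for H2AZ2, a histone variant, -1.81 for SLC6A6, a taurine transporter, and -1.85 for EGFL7, a secreted vascular factor. The planned count rose to 15413 without control replicate 1 and to 15434 without control replicate 2.

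The mean of both guide groups against control averages the effects of the 2 groups, with Cas9-VP64 and the guides possibly confounded in it. With the library factor 18 of 17061 genes passed in edgeR, 1 higher and 17 lower, with 1328 at an unadjusted p under 0.05. IL32 fell by 3.35 ± 0.15 on the log2 scale (adjusted p = 1.7e-06), and IFI44L by 3.49 ± 0.29 (adjusted p = 0.00033). TNFRSF9 (-2.3) and OAS3 (-2.14) had an adjusted p of 0.00018 each, and IFI6 (-2.08) of 0.00074. IRF9, a subunit of the complex that turns on interferon-stimulated genes, fell by 1.14 ± 0.14 (adjusted p = 0.011), and IFITM1, which blocks virus entry, by 1.12 ± 0.15 (adjusted p = 0.016). For all 7 of these genes the 5 guide libraries lay below both controls. NFKBIA, VCAM1, ERAP2, PLA2G4C and the noncoding LOC100272217 were lower as well. Chosen after their values were seen, TAPBP, TNC, IFIH1 (-1.04), IFIT1 (-0.97), both sensors or effectors against viral RNA, and EPSTI1 were lower and COL14A1 higher (1.06). Of the 5 guide libraries, 5 lay below both controls for TAPBP, 4 for TNC, IFIH1 and EPSTI1 and 3 for IFIT1. COL14A1 lay above both controls in 4. For IFIT1 both IL1RN libraries (6.93 and 3.92 CPM) lay between the controls (11.9 and 3.77 CPM).

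Interferon-stimulated genes fell as a group in the mean of both guide groups. In the planned model 38 of 39 were negative, with a median of -0.58 (camera, adjusted p = 6.5e-27; adjusted p = 0.086 with an estimated correlation), 0 lower over all genes and 12 when adjusted over the list alone. With the factor 37 were negative with a median of -0.54 (camera, adjusted p = 3.8e-30; adjusted p = 0.043 with an estimated correlation; fry, adjusted p = 0.0071), 8 lower over all genes and 23 when adjusted over the list alone. In each of the 7 fits without 1 library the list was lower by camera with the factor, with medians of -0.46 to -0.8, while adjusted p with an estimated correlation was 0.15 to 0.86. NF-kB response genes had a median of -0.53 (camera, adjusted p = 8e-08; adjusted p = 0.086 with an estimated correlation; 1 lower over all genes and 3 adjusted over the list alone), which missed without control replicate 1 (adjusted p = 0.082), and -0.37 with the factor (camera, adjusted p = 3.4e-09; adjusted p = 0.65 with an estimated correlation; 3 lower over all genes and 7 adjusted over the list alone). Ribosomal protein genes had a median of -0.13 and a mean of -0.12 but ranked higher by camera (adjusted p = 0.032; adjusted p = 0.92 with an estimated correlation), so the test and the median differ in sign, and -0.05 with the factor, ranked lower (camera, adjusted p = 0.023; adjusted p = 0.95 with an estimated correlation). Respiratory chain genes, at -0.23 in the planned model, had a median of -0.16 with the factor (camera, adjusted p = 3.2e-05; adjusted p = 0.65 with an estimated correlation).

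The planned edgeR model called 0 transcripts for the mean of both guide groups, with 282 at an unadjusted p under 0.05. DESeq2 called 12, all lower (270 unadjusted), the edgeR likelihood ratio test 18, all lower (374 unadjusted), and gene-symbol sums gave IL32 (adjusted p = 0.021). Transcripts with the smallest p had values of -2.36 for TNFRSF9, -3.45 for IFI44L, 1.01 for RORB and 0.75 for PAG1, an adaptor of T cell signalling. The planned count rose to 5529 without control replicate 1 and 11 without control replicate 2, and the count of 18 with the factor became 48 and 81 without control replicates 1 and 2, 89 and 163 without IL1RN replicates 1 and 2, and 6 without HBG replicate 2. IL32, OAS3, TNFRSF9 and IFI44L passed in all 7 such fits, while the other 14 each missed at least once (adjusted p of 0.052 to 0.27 where missed): 12 without control replicate 1, with IFI6 at -1.15, IFITM1 at -0.64 and IFIH1 at -0.68, the rest, TAPBP (-0.64) and LOC100272217 (-1.23), without control replicate 2, and 12 also without HBG replicate 2, all but IFI6 and TNC.

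The genes lower in both comparisons with control were IL32, IFI44L, IFI6, OAS3 and TNFRSF9, 5 shared calls from 6 and 15 with the library factor, where independent lists would share 0.0041. Both comparisons use the same 2 controls, which cannot be split into separate pairs. In 100 simulated draws with unchanged guide groups the shared calls averaged 0.04 (at most 1) with controls drawn anew and 4.76 (at most 10) with the controls as measured. The latter draws keep any real difference of the controls from the guide groups, which can be called again. They therefore do not give the sharing expected without such a difference. In all draws each gene was drawn independently, around the library factor that was then fitted or, for the planned model, around a common mean. The draws thus lacked the correlation between genes in the real libraries and any error of the factor. The average of 0.04 may therefore be too low a reference for the 5 shared calls. Across genes, which are not independent replicates, the log2 fold changes had an r of 0.38 and a covariance of 0.04, against an average r of 0.23 and covariance of 0.02 with controls drawn anew, and 0.33 and 0.03 with controls as measured. In the planned model 0 calls were shared, with an r of -0.44 and a covariance of -0.16 across transcripts, against simulated averages of 0.54 and 0.15 with controls drawn anew and 0.25 and 0.04 as measured. DESeq2 shared 9 lower calls. The 5 shared calls became 8 without control replicate 1, 11 and 14 without IL1RN replicates 1 and 2, and 3 without HBG replicate 2.

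**Figure D4:**
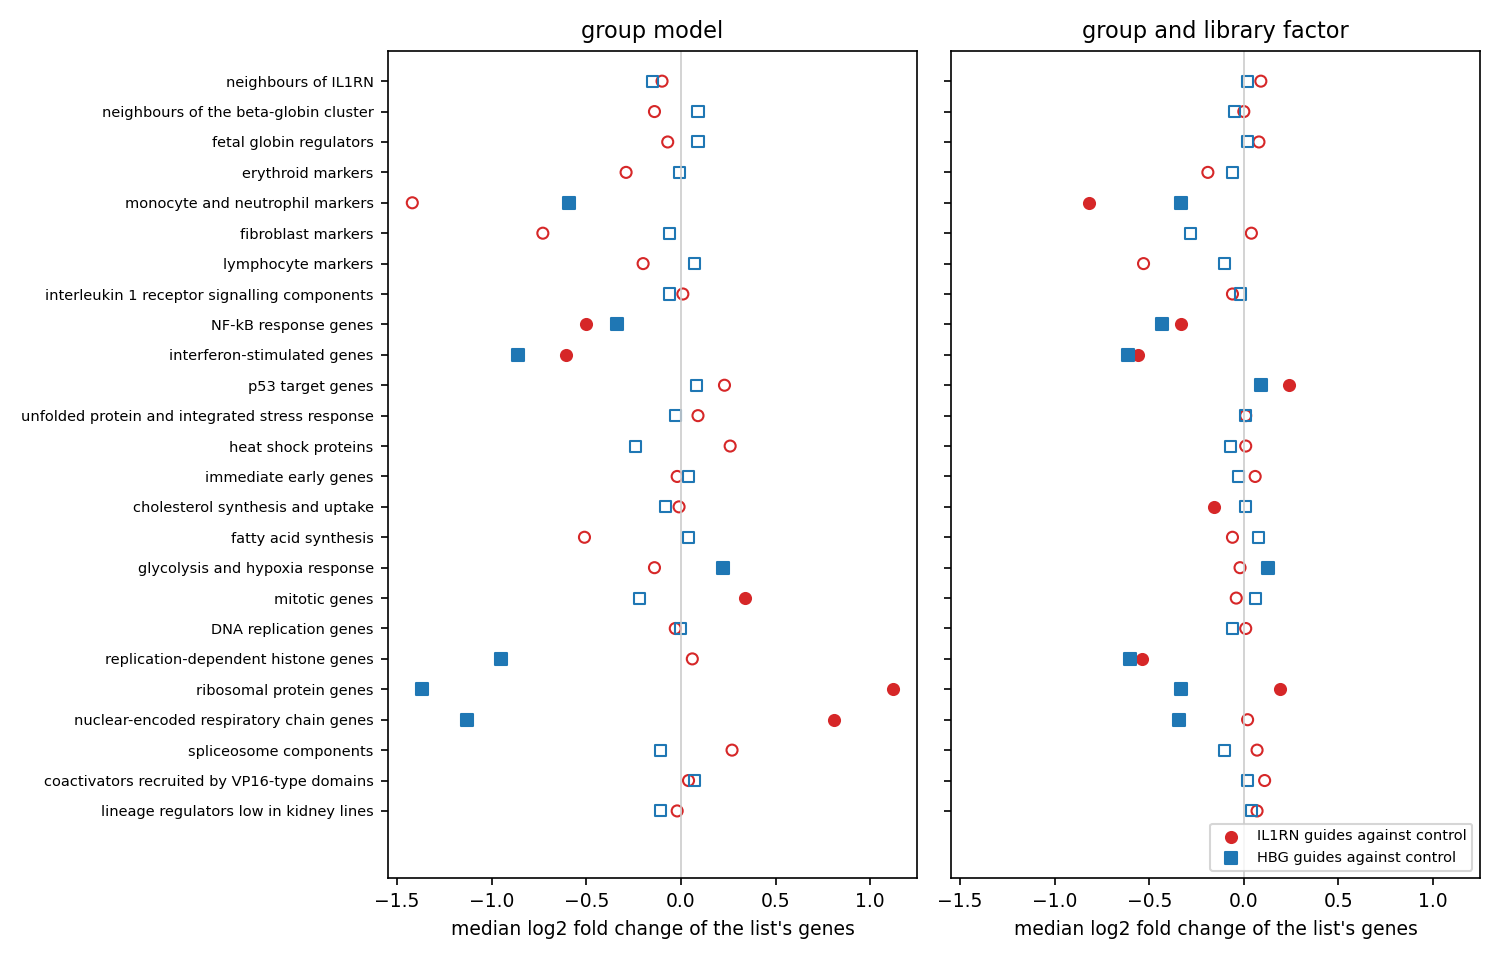
Median log2 fold change of each tested gene list with IL1RN guides (circles) and HBG guides (squares) against control, in the model with group alone (left) and with the library factor (right). Filled symbols have a camera adjusted p under 0.05. Ribosomal protein genes stand at 1.12 and -1.37 on the left and 0.19 and -0.33 on the right, while interferon-stimulated genes stand at -0.61 and -0.86 on the left and -0.56 and -0.61 on the right.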

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

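The contrast of IL1RN guides with HBG guides was planned; the library factor in it and the tests of the 3 patterns weighed here were chosen after the results were seen. IL1RN differed between the 2 guide groups by a test of the difference itself, with a log2 fold change of 8.47 (adjusted p = 0.022 with the library factor, and 0.15 on gene-symbol sums without it).

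One axis held most of the difference between libraries, with the controls on opposite sides. The guides a library received were not its whole cause, since the controls, which received no targeting guide, lay 0.82 apart on the axis fitted to all libraries and the IL1RN and HBG means 0.69, while a part played by the guides cannot be told apart, since the nearest IL1RN and HBG libraries lay 0.39 apart on it. Depth does not give it, since the controls' depths had a ratio of 1.06. The fitted trend on GC content and transcript length took 50.5% of the variance. It was not the whole cause of the axis, since 74.9% of the variance left after its removal still lay on a single axis. An effect of GC content or length in another form could leave such an axis too, and cannot be told apart. The labels give no batch to test, and no biological explanation was tested.

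Interferon-stimulated genes were lower in both guide groups than in control by camera, while with an estimated correlation the adjusted p was 0.77 (IL1RN guides), 0.24 (HBG guides) and 0.086 (mean of both groups) in the planned model and 0.045, 0.091 and 0.043 with the library factor. The axis shared by the libraries as the cause is argued against by the medians with the axis as a covariate. They were -0.56 (IL1RN guides) and -0.61 (HBG guides), against -0.61 and -0.86 without. In the mean of both groups the median was -0.54 with the covariate and -0.58 without. This mean decides little, since it lay 0.23 from the control mean on the axis, where the controls lay 2.09 apart. With 1 library left out the list did not pass there with an estimated correlation. With the fitted GC content and length trend removed, the median in the mean of both groups was -0.55. The weights of the axis rose with GC content, so this mean decides little about the trend as well. In the separate groups the list stayed lower by camera with the trend removed (adjusted p = 1.2e-13 with IL1RN guides and 3.6e-21 with HBG guides). With an estimated correlation the adjusted p was 0.11 and 0.051, so the trend cannot be excluded. Leukocytes in the control wells were checked with 8 leukocyte transcripts (S100A8, S100A9, TYROBP, AIF1, CD3D, CD3E, MS4A1 and IL7R), chosen after the result was seen. These held 2 reads in both controls together, where IL32 held 1564, which argues against leukocytes for these transcripts alone. Other planned markers held more, with 328 control reads for CD68, 283 for LYZ and 244 for CD8A. Each overlapped the guide libraries in level. CD68 had 3.97 and 3.63 CPM in the controls and 2.67 to 4.33 CPM with guides. LYZ had 3.66 and 2.95 CPM against 2.71 to 4.1 CPM, and CD8A 4.73 and 1.3 CPM against 0.878 to 3.64 CPM. The 18 lymphocyte and 20 monocyte and neutrophil markers had median control levels of 0.109 and 0.0961 CPM. The reads of CD68, LYZ and CD8A thus do not speak for leukocytes in the control wells. The tested monocyte and neutrophil markers as a list went the other way, so leukocytes cannot be excluded. Of 7 tested monocyte and neutrophil markers 7 were lower as well in the mean of both groups in the planned model (median of -1.01, camera, adjusted p = 7.9e-05, and 0.086 with an estimated correlation). With the library factor 6 were lower (median of -0.12, camera, adjusted p = 0.0012, and 0.58 with an estimated correlation). Cas9-VP64 with guides against empty plasmid as such cannot be told apart from an effect of the guides, since the labels give 0 groups with the Cas9-VP64 plasmid and no targeting guide and leave open whether the control received it. A response of control cells to their plasmid or its preparation, or a lower response with the activator, could each be behind it.

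Between IL1RN and HBG guides 9742 transcripts had an unadjusted p under 0.05. The axis shared by the libraries goes with this, since the differences between the controls and between the guide groups had an r of 0.94 across transcripts. With the axis as a covariate the number fell to 1021, but this fall cannot decide the cause. The IL1RN and HBG means lay 1.65 apart on the axis, so the covariate takes up part of their difference whatever its cause. Whether the guides moved the libraries along the axis cannot be told apart, since the nearest IL1RN and HBG libraries were 0.89 apart on it while the controls spanned 2.09. The difference may thus come from the axis, which was found and tested on the same data.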

How the results depend on the processing

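The library factor, the GC content and length trend and gene-symbol sums with the factor were chosen after the data were seen; the other alternatives were planned, except where they are combined with the factor. For the transcript counts of 0, DESeq2 gave 15 (IL1RN guides against control), 13 (HBG guides against control), 3607 (IL1RN against HBG guides) and 12 (mean of both groups); the likelihood ratio test 15, 18, 2623 and 18; the library factor 19, 25, 0 and 29; gene-symbol sums with the factor 6, 15, 1 and 18; and gene-symbol sums alone 0, 1, 0 and 1. With the GC content and length trend removed the counts were 0, 2, 0 and 9, and with the replicate block as well 0, 1, 3010 and 11, while the block alone gave 0 in each. At least 1 count in any library gave 6 for the mean of both groups, and only the groups compared gave 15451 for IL1RN against HBG guides. Leaving out 1 library gave 0 to 15221 (highest without control replicate 1), 0 to 11123 (control replicate 2), 0 to 15434 (control replicate 2) and 0 to 5529 (control replicate 1). Each of these highest counts came without a control, and the 2 controls differed most among replicates. Their mean squared standardized difference was 408, against 23.1 to 88.9 within the guide groups. Why the counts rose was not tested.

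For the counts with the library factor (6, 15, 1 and 18) at least 1 count in any library gave 10, 33, 1 and 36, DESeq2 13, 60, 0 and 56, the likelihood ratio test 27, 109, 1 and 127, the replicate block 29, 26, 0 and 98, the block with the GC content and length trend removed 40, 23, 3 and 115, and transcripts as deposited 19, 25, 0 and 29. Of the genes called, DESeq2 kept 5, 14, 0 and 18, and the block 5, 14, 0 and 18. Leaving out 1 library gave 4 to 258, 4 to 186, 0 to 324 and 6 to 163, and the cause was not tested. Named genes with the factor kept direction and side of the threshold in 384 of 400 values under other settings and in 195 of 280 with 1 library left out, and 0 reversed. Deviations from the group means of same-numbered libraries had correlations of 0.67, 0.67, 0.59, 0.49, -0.04 and -0.32, and control replicate 1 correlated best with HBG replicate 3 (0.77), so the numbers were not taken to pair the libraries and the block is given here alone. Under the block IL1RN with IL1RN guides against control had 4.29 (adjusted p = 1), and 4.27 (adjusted p = 1) with the GC content and length trend removed as well, its call against HBG guides was not made in either (1.64 and 1.35), and the NF-kB list with IL1RN guides against control went from an adjusted p of 0.047 to 0.068 in the planned model.

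The IL1RN log2 fold change of 6.29, for the transcript NM_000577, was 6.43 with DESeq2, 6.29 with the likelihood ratio test and 5.52 with the factor. These alternatives each passed the threshold. On gene-symbol sums it was 7.29 without the factor (edgeR, adjusted p = 0.51) and 6.8 with it, past the threshold. Leaving out 1 library gave 5.19 to 9.94 for NM_000577. The highest came without control replicate 1, where the control had 0 reads and the fitted value depends on the prior count. The bound for HBG1 (1.39) ranged from 0.21 to 1.92 and for HBG2 (1.77) from 0.6 to 2.18 with 1 library left out; the filters and the other tests gave no bound because both genes are below the filter or the test has none. Lists past camera numbered 5, 7, 3 and 6, and 0 in each with an estimated correlation and with fry; the library factor gave 6 for IL1RN against HBG guides. Leaving out 1 library gave 3 to 10 lists for IL1RN guides against control. Shared calls (0 on transcripts) were 9 with DESeq2 and 5 with the factor on gene-symbol sums, which changes both the model and the level. The latter became 3 without HBG replicate 2. Library size only moved the median of all transcripts to -0.26, 0.08, -0.37 and -0.13. Depth limits HBG1 and HBG2, with 3 to 6 reads per library.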

Other observations

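The gene lists were planned; the library factor beside them was chosen after the data were seen. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had medians with the factor of -0.54 with IL1RN guides (camera, adjusted p = 0.00011; adjusted p = 0.68 with an estimated correlation), -0.6 with HBG guides (camera, adjusted p = 0.00055; adjusted p = 0.81 with an estimated correlation) and -0.56 in the mean of both groups (camera, adjusted p = 1.5e-05; adjusted p = 0.65 with an estimated correlation), over 16 tested genes. In the planned model the medians were 0.06 (camera, adjusted p = 0.86), -0.95 (camera, adjusted p = 3.4e-06; adjusted p = 0.53 with an estimated correlation) and -0.5 (camera, adjusted p = 0.00071; adjusted p = 0.82 with an estimated correlation), and for IL1RN guides against control the direction of the median turned with the factor. H2BC21 had -0.83 ± 0.19 in the mean of both groups, past the threshold adjusted over the list alone (0.016) and not over all genes. Targets of p53, which respond to DNA damage, had medians with the factor of 0.24 (camera, adjusted p = 5.9e-05; adjusted p = 0.56 with an estimated correlation) with IL1RN guides, 0.09 (camera, adjusted p = 0.012; adjusted p = 0.81 with an estimated correlation) with HBG guides and 0.17 (camera, adjusted p = 9.2e-05; adjusted p = 0.65 with an estimated correlation) in the mean, over 28 genes. BTG2, which slows proliferation, had 0.5 ± 0.12 in the mean (0.041 adjusted over the list alone). In the planned model the p53 list had medians of 0.23 with IL1RN guides and 0.08 with HBG guides (camera, adjusted p = 0.22 for each), and a median of 0 and a mean of 0.02 in the mean of both groups (camera, adjusted p = 0.0097; adjusted p = 0.43 with an estimated correlation).

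Of 20 monocyte and neutrophil markers 7 were expressed enough to test. Their medians with the factor were -0.82 with IL1RN guides (camera, adjusted p = 0.0014; adjusted p = 0.56 with an estimated correlation), -0.33 with HBG guides (camera, adjusted p = 0.012; adjusted p = 0.59 with an estimated correlation) and -0.12 in the mean (camera, adjusted p = 0.0012; adjusted p = 0.58 with an estimated correlation), and in the planned model -1.42 (camera, adjusted p = 0.052), -0.59 (camera, adjusted p = 0.048; adjusted p = 0.53 with an estimated correlation) and -1.01 (camera, adjusted p = 7.9e-05; adjusted p = 0.086 with an estimated correlation). For IL1RN guides 1 member, CSF1R, had 0 reads, and with it at its bound the medians stayed at -1.42 and -0.82. CD14, a receptor for bacterial lipopolysaccharide, and ITGAM, an integrin, had -1.78 ± 0.37 and -1.97 ± 0.43 in the mean, each with 0.0025 adjusted over the list alone and not past it over all genes; CD14 stood at 0.726 CPM in control.

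Of the 25 lists tested, 14 passed camera in none of the 4 comparisons, without or with the library factor, with smallest adjusted p of 0.084 and 0.058. They include the neighbours of both targeted loci, with medians without the factor of -0.1 and -0.15 (IL1 cluster, 6 tested) and -0.14 and 0.09 (beta-globin cluster, 7 tested) for IL1RN and HBG guides against control. The others, with the same 2 medians, were fetal globin regulators (-0.07 and 0.09), erythroid markers (-0.29 and -0.01), fibroblast markers (-0.73 and -0.06), lymphocyte markers (-0.2 and 0.07), interleukin 1 receptor signalling components (0.01 and -0.06), the unfolded protein and integrated stress response (0.09 and -0.03), heat shock proteins (0.26 and -0.24), immediate early genes (-0.02 and 0.04), fatty acid synthesis (-0.51 and 0.04), DNA replication genes (-0.03 and 0), coactivators recruited by VP16-type domains (0.04 and 0.07) and lineage regulators low in kidney lines (-0.02 and -0.11). Among their members, CALR, an endoplasmic reticulum chaperone, had -0.6 ± 0.11 with the factor in the mean of both groups (0.0081 adjusted over the list alone). HSPB1, a small heat shock protein, had -0.65 with HBG guides (0.027 adjusted over the list alone). Neither passed over all genes. The targeted genes and 4 of the 12 other globin genes were too few to test as lists; with the factor the latter had values in IL1RN guides against control of -0.49 for HBA1, 0.15 for HBA2, -0.2 for HBQ1 and 0.05 for CYGB. None of the 13 mitochondrially encoded genes is in the table.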
